A study of Mus musculus with 6 samples.

How the data were processed

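Gene expression was measured by RNA sequencing in mouse 3T3 fibroblasts with a control or an NNMT construct, 3 libraries each. The labels name total RNA, a Qiagen column kit and NEB library preparation, and whether poly-A RNA was selected is not given in the sources used here. Per the submitters' processing notes, the tools named are CASAVA and STAR 2.5 and the genome build is mm10. The read counter, the annotation release, the strandedness of counting and whether reads or fragments were counted are not given in the sources used here. The authors deposited 1 table with a column of values per library and no unit in its header, so that the unit was inferred. The deposited values behave as FPKM: within a gene they are whole multiples of a step, and the step times the length of the gene's longest GENCODE M21 transcript gave the same library total for 15102 of 20528 genes above 0 (73.6%). Whole reads were recovered from these steps for 20528 of 20528 genes above 0, with a tolerance of 0.01 of a read, and summed to between 99.85% and 99.89% of the implied library totals. A read on 1 kb was worth 0.0250 to 0.0316 FPKM. No share of counts in a single sample is reported, so no binomial intervals are given. Symbols and coordinates are from GENCODE M21 on GRCm38, the assembly that mm10 names, and 34490 of 35275 row identifiers were paired with a gene there. Gene coordinates are those of the annotation and not of the deposited table.

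Of the 6 columns, 5 carry a replicate number. The NNMT column without one was used as the remaining NNMT library and is called the unnumbered NNMT library. Chi-square tests on recovered reads differed for each pair of libraries of a group (6.07 to 21.9 per degree of freedom), so none was treated as a copy of another. These tests cover counting error alone and do not tell separate cultures from repeated preparations of the same RNA. The table holds no fold change or p-value of the authors, so no comparison with their own calls was made. The design fixed before the data were examined gave one test for counts and another for normalized values, and the second was used.

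Genes with a mean of at least 1 FPKM over the 6 libraries were tested, on log2(FPKM + 1), with limma 3.58.1 in R 4.3.3, with a mean-variance trend and robust moderation, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold values in the text are ratios of group mean FPKM, given only where each group had at least 10 reads. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, and adjusted over the 24 of 28 lists with at least 5 tested members. Of these, 9 passed with camera at the preset correlation, 0 with an estimated correlation and 20 with fry, which asks whether the genes of a list move one way and compares them with no other genes. A call of camera in the text is thus a statement at the preset correlation. Counts per list are over all genes tested. For the 28 lists fixed beforehand they are the same adjusted over the list alone, except where another count is given. Pnp, Prmt1 and Snrpn were not used, since these symbols were not found among the annotated genes of the table.

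The script for the tests was tested on simulated data with 200 changed genes among 10759 tested, at the larger dispersion of the groups (0.0024). It recovered 86.0% of 50 genes changed 1.25-fold, 94.0% at 1.5-fold, 92.0% at 2-fold and 98.0% at 4-fold, with 18 false calls. The simulation gave all genes the same dispersion and changed far fewer genes than the 7140 called in the data. These shares need not hold for the real libraries. In a second simulation, camera called a list of 30 genes changed 1.25-fold and did not call an unchanged list of 30.

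The genes named were fixed by a rule before the data were examined. It takes Nnmt first. It then takes the 10 largest rises and the 10 largest falls among named protein-coding genes that pass the threshold, reach a mean of 5 FPKM in the higher group and do not overlap between the groups. From each list it takes up to 4 members with the smallest adjusted p, or up to 2 as values where fewer than 2 pass. Other genes are said to be named after their values were seen. Not every gene that the rule takes is reported here. The spans of some named genes overlap another expressed gene (Sulf2, Slc19a1, Aldh1l2, Psph, Parp3, Sirt3, Naprt, Lig1, Kif4, Cdc20, Cdc25b, Rrm2b, G6pdx, Kdm1a, mt-Nd5, mt-Nd6 and Jun). Their values, and those of genes with close relatives or processed copies elsewhere (ribosomal protein genes, Ftl1, and the X and Y pairs such as Ddx3x and Ddx3y), are less certain, because the strand and multi-mapping rules of the counting are not known.

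Alternatives fixed before the data were examined were quantile normalization, limma without trend or without robust moderation, no filter, a mean of at least 5 FPKM, pseudocounts of 0.1 and 10, an adjusted p under 0.01, an absolute log2 fold change of at least 1, leaving out each library, and a replicate block. Chosen after the data were seen were limma-voom on recovered reads, scaling by medians of ratios, removal of the genes of X and Y or of X, Y, 4 and 16, values centred per chromosome in each library, replicates 2 and 3 without the block, and 7 further gene lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.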

Results

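RNA from mouse 3T3 cells, an immortalised embryonic fibroblast line, was sequenced in 6 libraries. Of these, 3 came from cells carrying an overexpression construct for nicotinamide N-methyltransferase (NNMT), the enzyme that methylates nicotinamide with S-adenosylmethionine as methyl donor, and 3 came from cells carrying a control construct. The cells had grown for 48 h in medium with 10 µM methionine and 10% dialyzed serum. The comparison asks which genes respond to NNMT in this medium. The deposited gene levels carry no unit and were read as FPKM from their values, and 33990814, 38877521 and 31620054 counted reads or fragments (reads in what follows) were recovered from these values in control replicates 1, 2 and 3. In the NNMT cells 39990972 were recovered in the library without a replicate number, 35294532 in replicate 2 and 36296380 in replicate 3. A single read on a gene of 1 kb was worth 0.0250 to 0.0316 FPKM. In all of what follows n = 3 per group, values are mean ± SD in FPKM, and log2 fold changes are NNMT against control on log2(FPKM + 1), a scale that understates the change of low genes.

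Nnmt itself was higher in the cells labelled NNMT. The gene (ENSMUSG00000032271, chromosome 9, 48591877 to 48605153 in GRCm38, minus strand) stood at 7.61, 5.25 and 6.51 FPKM in control replicates 1, 2 and 3. It stood at 15.7 FPKM in the unnumbered NNMT library, 15.03 in replicate 2 and 18.3 in replicate 3. The means were 6.45 ± 1.18 and 16.3 ± 1.70, a 2.53-fold difference resting on 698 reads in the control libraries and 1903 in the NNMT libraries. The log2 fold change was 1.23 (SE 0.108, limma adjusted p = 4.75e-06), and every NNMT library lay above every control library. An exact two-sided permutation test gave p = 0.1, the smallest p that 3 against 3 allows. The log2 fold change was 0.68 with a pseudocount of 10, still a rise and smaller by the construction of that scale. In the same test 168 genes rose by more than Nnmt. The species and codon usage of the construct are not given in the sources used here, and whether these values count the transcripts of the construct in full is not known.

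The transcriptomes of the 2 groups differed widely, and the 10 largest rises under the naming rule were each more than 10-fold. Serpine2 (ENSMUSG00000026249, chromosome 1, 79794197 to 79861180), a secreted inhibitor of thrombin and urokinase, went from 0.692 ± 0.0252 to 41.5 ± 4.98 FPKM. On the log2(FPKM + 1) scale this was the largest rise among the named protein-coding genes under the naming rule (log2 fold change 4.65, SE 0.079, limma adjusted p = 8.73e-11). Ccn5, a matricellular protein, rose 24.9-fold to 18.4 ± 0.919 FPKM, and Sulf2, an extracellular sulfatase that acts on heparan sulfate, rose 14.5-fold to 32.9 ± 3.75 FPKM. Slpi, a secreted inhibitor of leukocyte proteases, rose 11.0-fold to 62.0 ± 8.06 FPKM. The secreted Wnt-binding proteins Sfrp2 and Sfrp1 rose 39.1-fold and 20.7-fold, to 10.9 ± 1.64 and 10.8 ± 2.30 FPKM. Lmcd1, a LIM domain protein, reached 8.48 ± 1.79 FPKM from 0.114 ± 0.0576, by ratio a larger rise than that of Serpine2 (74.1-fold against 60-fold). Islr rose 14.2-fold from 1.06 ± 0.342 FPKM. The other 2 of the 10 largest rises were the Y-linked genes Ddx3y, an RNA helicase (18.2-fold, to 49.5 ± 2.51 FPKM), and Eif2s3y, a translation initiation factor subunit (16.4-fold, to 25.7 ± 0.944 FPKM).

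Among the 10 largest falls, Rhox5 (ENSMUSG00000095180, X chromosome, 37804842 to 37808876), a homeobox gene, dropped from 88.2 ± 3.29 to 1.48 ± 0.542 FPKM (log2 fold change -5.19, SE 0.132, adjusted p = 1.15e-09). Gpr149, an orphan G protein-coupled receptor, was 151-fold lower at 0.120 ± 0.0778 FPKM (237-fold without NNMT replicate 2), and Vip, the vasoactive intestinal peptide, was 43.7-fold lower, from 17.6 ± 1.87 FPKM in control cells. Cd34, a surface sialomucin, dropped from 87.8 ± 2.26 to 6.54 ± 0.226 FPKM. Agtr2, the X-linked type 2 angiotensin II receptor, went from 7.12 ± 1.09 to 0.0110 ± 0.00502 FPKM, with 2424 reads in the control libraries and 4 in the NNMT libraries. Tusc1, on chromosome 4, and Renbp, on X, were 92.9-fold and 70.2-fold lower, with 12 and 18 reads in the NNMT libraries. The cell surface protein mesothelin (Msln), the water channel Aqp1 and the growth factor Igf2 were 8.56-fold, 8.11-fold and 7.62-fold lower, from 31.4 ± 2.01, 18.1 ± 0.788 and 20.4 ± 2.56 FPKM in control cells. All 20 genes in this and the preceding paragraph passed the adjusted p threshold of 0.05 with no overlap between the groups. The naming rule requires both, so this adds no support for them.

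**Figure D1:**
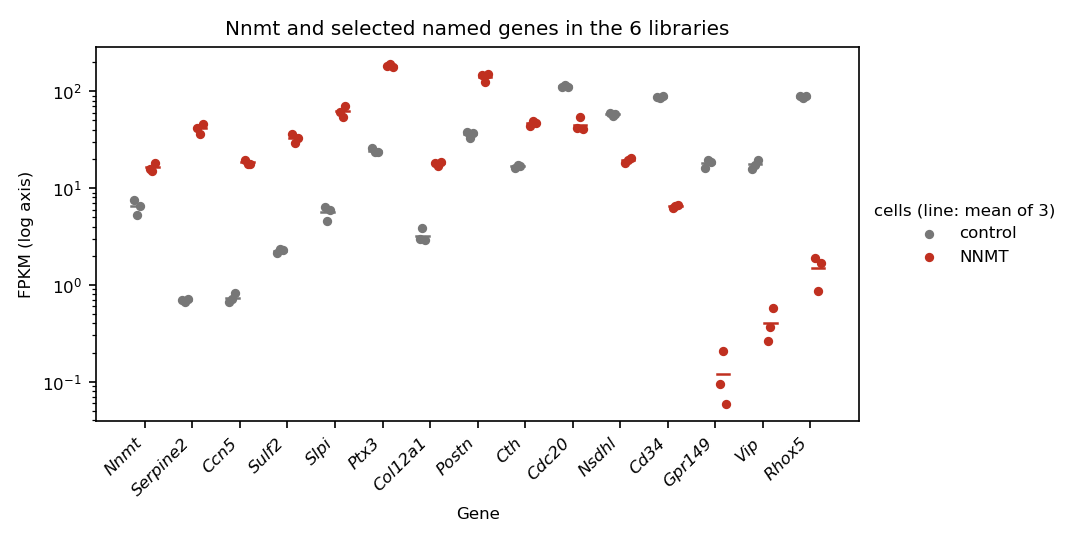
FPKM (log axis) of Nnmt and 14 other named genes in each of the 6 libraries, with 1 point per library, control in grey, NNMT in red and a line at the mean of 3. Nnmt differs 2.53-fold, Serpine2 rises from 0.692 to 41.5 FPKM, and Gpr149 falls from 18.2 to 0.120 FPKM.

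Of 10882 genes tested with limma, 3806 were higher and 3334 were lower in NNMT cells at an adjusted p under 0.05. More genes were lower than higher with medians of ratios scaling (3565 higher and 3609 lower) and with limma-voom on recovered reads (3557 and 3616), but not under quantile normalization (3607 and 3565). The median absolute log2 fold change of these 7140 genes was 0.36. At an absolute log2 fold change of at least 1 the counts were 257 higher and 192 lower. The groups did not overlap for 7604 genes, 69.9% of those tested, where chance gives 10%. Libraries of a group correlated at r = 0.995 to 0.998 across genes, and libraries of different groups at 0.956 to 0.964. The first principal component held 90.9% of the variance and separated the groups. The submitters call the samples biological replicates, but nothing says whether the cells of a group were transduced separately. The p-values then measure only the spread between these cultures, and any difference between 2 single starting populations counts as an NNMT difference.

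The changes were not spread evenly over the chromosomes. Of 338 tested X-linked genes, 305 fell and 8 rose, and the median log2 fold change was -0.70 with an interquartile range from -0.91 to -0.49. All 7 tested genes that the annotation places on Y rose. Ddx3y, Eif2s3y, Kdm5d and Uty, which lie on the short arm of Y and have X-linked relatives, rose 13.3-fold to 18.2-fold (Kdm5d and Uty are named here after their values were seen). The other 3 tested genes placed on Y, also named after their values were seen, rose 34.5-fold (Gm3376), 25.4-fold (Gm29650) and 1.87-fold (Gm47283). Gm47283 stood at 124 ± 6.44 FPKM in control cells, where Ddx3y stood at 2.72 ± 0.258 FPKM. Whether the reads of Gm47283 come from Y alone is not known. On chromosome 4, 390 of 688 genes fell (median -0.23), and on chromosome 16, 222 of 347 rose (median 0.29). The other autosomes had medians from -0.17 (chromosome 12) to 0.16 (chromosome 8). Each of the 12 windows of 10 Mb along X with at least 15 tested genes had a median between -0.84 and -0.54. On chromosome 4 the 8 windows from 80 Mb onward had medians from -0.45 to -0.24, and those before 80 Mb had medians from 0.01 to 0.24. Steps between windows also appeared on other chromosomes. On chromosome 16 the windows before 30 Mb had medians from 0.125 to 0.188 and those from 30 Mb had medians from 0.376 to 0.589. On chromosome 2 the windows before 20 Mb had medians of 0.20 and 0.24. Its windows between 20 and 140 Mb had medians from -0.23 to -0.02 and those from 140 Mb had medians from 0.11 to 0.30. On chromosome 7 they were -0.22 to -0.04 before 90 Mb and 0.11 to 0.21 beyond. Tests of each chromosome's genes with camera gave adjusted p = 1.41e-37 for X, 5.56e-08 for chromosome 4 and 9.61e-09 for chromosome 16. With an estimated correlation these became adjusted p = 0.0369, 0.0369 and 0.0841. Smaller shifts of other chromosomes passed too. In all, 13 chromosomes (1, 3, 4, 5, 8, 9, 12, 15, 16, 17, 19, X and Y) passed camera, and 7 (4, 5, 8, 17, 19, X and Y) passed with an estimated correlation. On chromosomes 12 and 17, 51.5% and 49.4% of tested genes fell, and on chromosomes 5 and 8, 51.6% and 52.4% rose. X and chromosome 4 together held 20.8% of the genes that fell. Without the genes of X, Y, 4 and 16, 3431 genes were higher and 2569 lower, a setting chosen after the data were seen. The values were not rescaled for this setting, where the median log2 fold change was 0.044, so part of this surplus may come from scaling.

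**Figure D2:**
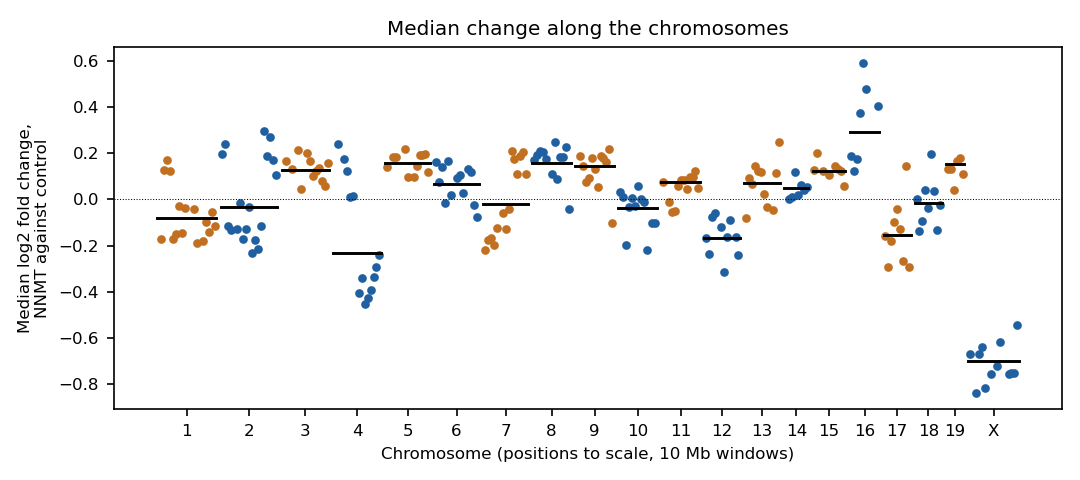
Each point is the median log2 fold change (NNMT against control) of the genes in each 10 Mb window with at least 15 tested genes, plotted along chromosomes 1 to 19 and X in alternating colours, with a black line at the median of each chromosome. The 12 windows of X lie between -0.84 and -0.54, and chromosome 4 steps from positive medians before 80 Mb to negative medians beyond it.

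Most of the tested collagen and matrix genes rose. Of 42 members of the list, 31 rose and 6 fell, with a median log2 fold change of 0.48 (32 and 6 when adjusted over the list alone). The fallers included the small proteoglycan Bgn (X-linked, 1229 ± 32.2 to 745 ± 37.9 FPKM), Fbln5 and Col16a1, which are named after their values were seen. The strongest by p were Col12a1, a collagen that binds fibril surfaces (5.55-fold, to 18.0 ± 1.03 FPKM), Lox, which cross-links collagen (2.06-fold, to 808 ± 15.9 FPKM), Postn (3.90-fold, to 141 ± 15.2 FPKM) and the collagen prolyl hydroxylase P4ha3 (2.47-fold, to 37.9 ± 2.22 FPKM). Tested as a set with camera, the list had adjusted p = 1.15e-05, and adjusted p = 0.557 with an estimated correlation. The list of proteases and their inhibitors also leaned upward, with 15 of 27 members higher and 4 lower (median 0.25). Ctsk, a collagen-degrading cathepsin, rose 5.94-fold to 18.6 ± 0.381 FPKM and Mmp9 rose 10.1-fold to 23.4 ± 2.71 FPKM, beside Serpine2. Plau, the urokinase gene, was among the 4 that fell (2.48-fold lower, to 10.9 ± 0.392 FPKM), with Adam17, Timp1 and Ctsb, which are named after their values were seen. For this list camera gave adjusted p = 0.0169, and adjusted p = 0.557 with an estimated correlation.

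Genes of the ATF4 response, which cells raise when amino acids are scarce or the endoplasmic reticulum is stressed, were higher. Of 34 tested members, 25 rose, and 2 (Sesn2 and Atf5, named after their values were seen) fell, with a median of 0.27. Cth, which makes cysteine from cystathionine, rose 2.80-fold to 46.8 ± 2.97 FPKM. Vldlr rose 2.71-fold, Herpud1, a factor of endoplasmic reticulum protein degradation, rose 1.71-fold, and Slc3a2, the shared chain of several amino acid transporters, rose 1.71-fold to 208 ± 10.9 FPKM. As a set these genes had camera adjusted p = 2.01e-05, and adjusted p = 0.343 with an estimated correlation.

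Cell division genes were lower. Of 38 tested mitosis genes, 37 fell and none rose (38 fell when adjusted over the list alone), with a median of -0.59. Only Tpx2 missed the threshold over all genes, at a log2 fold change of -0.20. Cdc20, an activator of the anaphase-promoting complex, went from 112 ± 2.62 to 45.3 ± 7.35 FPKM, and the phosphatase Cdc25b went from 26.1 ± 0.842 to 12.6 ± 1.47 FPKM. The kinesins Kif4 and Kif2c were 2.57-fold and 2.07-fold lower. Kif4 is X-linked, and Cdc20 and Kif2c lie on chromosome 4; these are the only 3 of the 37 on those chromosomes, and the list's median outside X, Y, 4 and 16 was -0.57. The camera test gave adjusted p = 1.81e-10, and adjusted p = 0.557 with an estimated correlation. Of 42 tested replication and S phase genes, 20 fell and 7 rose (median -0.13). Pola1, Lig1, Clspn and Uhrf1 were 2.09-fold, 1.58-fold, 1.75-fold and 1.58-fold lower, and 5 of the 20 lay on X or 4. For this list camera gave adjusted p = 0.00539, and adjusted p = 0.646 with an estimated correlation.

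Cholesterol synthesis genes fell in 21 of 24 cases with none higher (median -0.50). The sterol enzymes Nsdhl and Ebp, both X-linked, were 2.98-fold and 2.99-fold lower. Acat2, which condenses acetyl-CoA, went from 146 ± 2.12 to 70.1 ± 0.226 FPKM and Pmvk, phosphomevalonate kinase, was 2.08-fold lower at 18.4 ± 0.354 FPKM. The median of the 21 members outside X, Y, 4 and 16 was -0.42. The camera test gave adjusted p = 3.47e-08, and adjusted p = 0.522 with an estimated correlation. Ribosomal protein genes fell in 39 of 53 cases (40 when adjusted over the list alone) and rose in none, with a median of -0.23. Rps4x, on X, was 2.30-fold lower, Rps6, on chromosome 4, was 1.63-fold lower, and Rps16 was 1.47-fold lower. The camera call (adjusted p = 3.47e-08, and adjusted p = 0.557 with an estimated correlation) was lost under quantile normalization, where the median was -0.04 (adjusted p = 0.199, the highest of 20 alternatives that reached down to 4.42e-11).

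Imprinted and germline genes changed in all 11 tested cases, 8 downward and 3 upward (median -0.63). Besides Rhox5 and Igf2, Dlk1, a paternally expressed surface protein, went from 374 ± 39.1 to 130 ± 12.3 FPKM, and Peg3 was 2.01-fold lower. H19, the noncoding RNA next to Igf2, rose from 2.13 ± 1.17 to 41.2 ± 7.12 FPKM, and Plagl1 and Grb10 also rose; these 3 are named after their values were seen. The camera test gave adjusted p = 0.0159, and adjusted p = 0.557 with an estimated correlation, and the call was lost with no filter on low values (adjusted p = 0.0653, median -0.02), the highest of 20 alternatives with a range from 0.00433. Immediate early and heat shock genes fell in 17 of 26 cases and rose in 5 (median -0.25). The transcription factors Jun, Egr3 and Egr1 were 2.00-fold, 1.98-fold and 1.99-fold lower, whereas Myc rose 1.56-fold to 96.8 ± 4.54 FPKM. The other 4 that rose were Egr2, Dusp1, Klf2 and Hsp90b1, named after their values were seen. For this list camera gave adjusted p = 0.0227, adjusted p = 0.557 with an estimated correlation, and adjusted p = 0.054 under quantile normalization with the median still at -0.25, the highest of 20 alternatives with a range from 0.00382.

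The lists closest to the reaction that NNMT catalyses moved in both directions. Of 26 genes of the S-adenosylmethionine cycle and polyamine synthesis, 7 rose and 13 fell (median -0.13, camera adjusted p = 0.234). Apart from Cth, the strongest were falls of spermine synthase Sms (2.44-fold), the polyamine acetyltransferase Sat1 (2.30-fold) and Mtap, which salvages methylthioadenosine (1.84-fold). Sms and Sat1 are X-linked and Mtap is on chromosome 4. In all, 5 of the 13 that fell lay on X or 4, and the median of the 19 members outside X, Y, 4 and 16 was 0.00. Folate cycle and serine synthesis genes rose in 9 and fell in 4 of 21 cases (median 0.08, adjusted p = 0.277), with the folate carrier Slc19a1 2.24-fold, the purine synthesis enzyme Gart on chromosome 16 1.72-fold, Aldh1l2 1.52-fold and Psph 1.48-fold higher. Among 19 genes of nicotinamide and NAD metabolism, 7 rose and 5 fell (median 0.06, adjusted p = 0.809). Parp3, Sirt3 and Naprt rose 1.88-fold, 1.70-fold and 1.91-fold, and the NAD kinase Nadk was 1.34-fold lower. Of 54 histone and DNA methylation enzymes, 16 rose and 23 fell (median -0.04, adjusted p = 0.234). The X-linked genes Phf8, Suv39h1 and Kdm6a were 2.11-fold, 2.12-fold and 2.06-fold lower and Kdm1a on chromosome 4 was 1.42-fold lower, and 7 of the 23 lay on X or 4. None of these 4 lists passed camera, and by fry each did (adjusted p = 0.00882 to 0.0145).

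**Figure D3:**
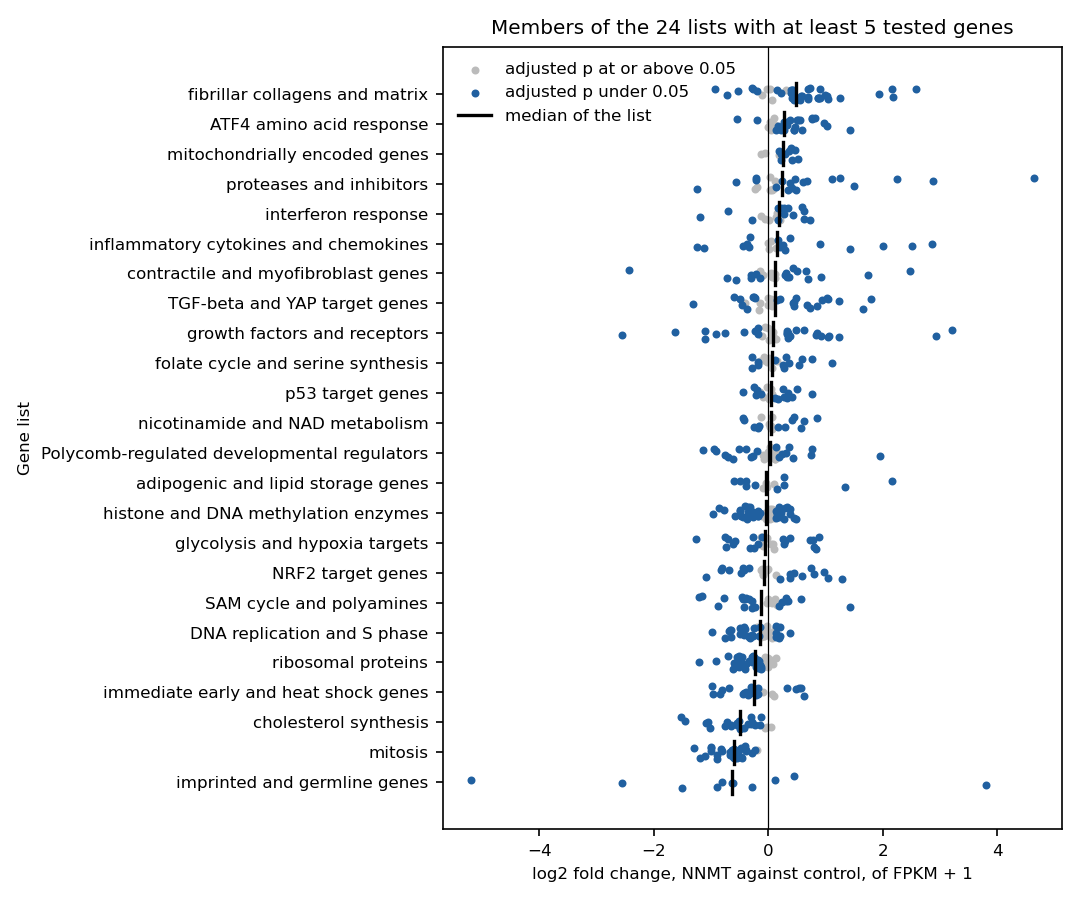
Log2 fold change (NNMT against control, FPKM + 1) of each tested member of the 24 gene lists with at least 5 tested members, with blue points for adjusted p under 0.05, grey points for the rest and a black bar at the list median. Mitosis (median -0.59) and cholesterol synthesis (median -0.50) lie below 0, and the matrix (0.48) and ATF4 (0.27) lists lie above it.

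Several other lists held large changes in single genes and did not pass camera. By fry, which compares a list with no other genes, each of the 5 lists in this paragraph passed (adjusted p = 0.000621 to 0.0134). Among 20 tested cytokine genes, 10 rose and 6 fell (median 0.15, adjusted p = 0.316). Ptx3, a secreted pattern recognition protein, rose 7.54-fold to 184 ± 6.60 FPKM, the chemokines Cxcl5 and Ccl9 rose 8.60-fold and 6.48-fold, and Il11 was 2.99-fold lower. Contractile genes rose in 11 and fell in 7 of 24 cases (median 0.12, adjusted p = 0.372). Myl9 and Mylk, the myosin light chain and its kinase, rose 3.50-fold and 12.3-fold, Tpm2 rose 1.58-fold, and X-linked Fhl1 went from 4.64 ± 0.614 to 0.0360 ± 0.0291 FPKM (129-fold lower with 11 reads in the NNMT libraries, 241-fold without NNMT replicate 3). Among 30 TGF-beta and YAP target genes, 15 rose and 8 fell (median 0.12, adjusted p = 0.234), with F3, Tgfbi and Tgfbr2 3.26-fold, 4.01-fold and 2.42-fold higher and Id2 2.69-fold lower. Growth factors and receptors rose in 16 and fell in 10 of 35 cases (median 0.09, adjusted p = 0.277), among them Fst, 3.38-fold higher. Of 20 interferon response genes, 11 rose and 3 fell (12 and 3 when adjusted over the list alone; median 0.19, adjusted p = 0.221). B2m and Irgm1 were 1.62-fold and 2.93-fold lower, Ifi27 and Isg20 rose 1.56-fold and 1.59-fold, and Stat2, named after its value was seen, was the third that fell.

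In lipid storage genes, 5 of 14 rose and 5 fell (median -0.03, adjusted p = 0.845), with Lpl and Dgat2 5.62-fold and 2.96-fold higher and Fasn and Elovl6 1.53-fold and 1.42-fold lower. Glycolysis and hypoxia genes rose in 9 and fell in 11 of 28 cases (median -0.06, adjusted p = 0.471). Pgk1, on X, and Eno1, on chromosome 4, were 2.41-fold and 1.67-fold lower, and Adm and Ndrg1 rose 1.91-fold and 1.85-fold. Among 27 NRF2 targets, 10 rose and 8 fell (median -0.07, adjusted p = 0.845). Ftl1 went from 2249 ± 42.7 to 1063 ± 33.6 FPKM and X-linked G6pdx was 1.81-fold lower, whereas Osgin1 and Abcc4 rose 3.44-fold and 2.44-fold. Of 21 p53 targets, 9 rose and 5 fell (median 0.06, adjusted p = 0.594), with Plk2, Rrm2b and Zmat3 1.71-fold, 1.63-fold and 1.27-fold higher and Bax 1.36-fold lower. Of 32 tested developmental regulators that Polycomb controls in many tissues, 9 rose and 11 fell (median 0.03, adjusted p = 0.697). Foxf1 rose 6.79-fold to 6.73 ± 0.657 FPKM, and Nkx2-5, Wnt5a and Foxc2 were 2.45-fold, 2.06-fold and 2.07-fold lower. By fry the p53 (adjusted p = 0.00437) and glycolysis lists (0.011) passed, and the lipid storage (0.349), NRF2 (0.256) and Polycomb lists (0.231) did not. The mean and the median differed in sign for the lipid storage (mean 0.15), NRF2 (mean 0.05) and Polycomb lists (mean -0.03), and camera pointed down for each.

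Among mitochondrially encoded genes, 9 of 12 rose and none fell (median 0.27, camera adjusted p = 0.0915, fry adjusted p = 0.0536). The examples were mt-Co1 (1.44-fold), mt-Co2 (1.34-fold), mt-Nd5 (1.38-fold) and mt-Nd6 (1.34-fold), of which mt-Nd5 and mt-Nd6 lie on opposite strands and overlap. The list passed under quantile normalization (adjusted p = 0.0157), with no filter on low values (0.0267), without control replicate 2 (0.0321) and without the unnumbered NNMT library (0.0283), and its adjusted p over 19 alternatives reached 0.188. Markers of other cell types were close to absent. No epithelial marker reached the test, and the highest value in any library was 1.04 FPKM. Of 12 endothelial markers only Flt1 was tested, and it rose 1.87-fold to 3.22 ± 0.0751 FPKM. Of 20 immune markers, Cd14 was 2.15-fold lower at 2.09 ± 0.420 FPKM and Cd68 stood at 1.80 ± 0.285 in control and 1.397 ± 0.334 in NNMT cells (adjusted p = 0.0934), and passed under quantile normalization (0.0338) and with values centred per chromosome (0.0373). Of 16 muscle and neural markers, Tubb3 went from 3.63 ± 0.167 to 0.0709 ± 0.0493 FPKM. The other 2 tested did not pass. Acta1, at 2.34 ± 2.30 and 1.09 ± 0.402 FPKM, had an adjusted p of 0.375, and its direction turned without control replicate 1 (log2 fold change 0.04).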

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

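The counts of genes, the Nnmt difference and the number of gene lists past the threshold stayed within 1.5 times of the reported values under all alternatives but those named here; voom, medians of ratios, the chromosome settings and replicates 2 and 3 without a block were chosen after the data were seen. The 7140 genes called became 5492 to 7911 under other scalings, filters and pseudocounts, 5754 at an adjusted p under 0.01, and 6390 to 7120 when a library was left out. Only the requirement of an absolute log2 fold change of at least 1 lowered them further, to 449 (257 higher and 192 lower), by its construction. The surplus of higher over lower genes (3806 against 3334) turned with medians of ratios (3565 against 3609) and limma-voom (3557 against 3616). It did not turn under quantile normalization (3607 against 3565). The median log2 fold change of all tested genes was 0.028 in the main fit. It was 0.003 with medians of ratios, 0.004 with limma-voom and 0.006 under quantile normalization. The surplus thus depends on the scaling of the libraries, and a cause beyond that was not tested. In the fit by limma-voom on recovered reads, 6847 of its 7173 calls were also among the 7140, all in the same direction. Centred per chromosome, 5567 of 6601 calls were shared and 5492 of these kept their direction. Nnmt stayed past the threshold with log2 fold changes of 0.68 to 1.36, the lowest with a pseudocount of 10. The 9 gene lists past the threshold became 0 with camera at an estimated correlation, where the smallest adjusted p was 0.343. With fry, which asks another question, 20 passed, and otherwise 8 to 10 did. The loss came with the switch from the preset to an estimated correlation, and what in that switch caused it was not tested. The share of the first principal component, 90.9%, was 87.1% without a filter, 92.0% at a mean of at least 5 FPKM, 89.8% without chromosomes X, Y, 4 and 16, 89.6% centred per chromosome, and 90.7% to 92.9% when a library was left out; the cause was not tested. Of 114 named genes besides Nnmt, only Acta1, not called, changed direction: its log2 fold change of -0.48 was 0.045 without control replicate 1 and 0.082 on replicates 2 and 3 both with and without the replicate block, since its control mean rests on that library. Leave-one-out values for Acta1 ran from -0.842 to 0.045. Cd68 passed under quantile normalization (-0.30) and centred per chromosome (-0.30). Calls of G6pdx, Kdm6a, mt-Co2 and mt-Nd6 were lost when values were centred per chromosome, which removes each chromosome's own shift. The labels number the replicates 1 to 3 in both groups, but 1 NNMT column carries no number, so the replicate block was fitted on the 4 libraries numbered 2 and 3. The replicate block called 7109 genes (3910 higher and 3199 lower) against 6628 without the block. The deviations of same-numbered libraries correlated at 0.21 for number 2 and 0.11 for number 3, and those of control replicate 1 and the unnumbered NNMT library at 0.31. Control replicate 3 correlated better with NNMT replicate 2 (0.21) than with its own number, no label says that a number marks a shared batch or day, and whether the numbers pair the samples stays open. Depth limits genes near 1 FPKM most, and genes with fewer than 10 reads in a group were given no ratio.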

Other observations

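The 7 gene lists in this and the next paragraph, and the later tests on X and Y, on chromosome 9 and on matched lists, were chosen after the results had been seen. Counts of these lists are therefore given without a set test. Of 20 matrix genes known from adventitial and tendon fibroblasts 11 were tested, among them Islr, and 9 rose and 1, Efemp1, fell (median log2 fold change 2.03). Dermatopontin (Dpt) rose from 0.138 ± 0.0505 to 7.10 ± 1.57 FPKM, the small proteoglycans Ogn and Fmod rose 8.67-fold and 11.7-fold, and the microfibril protein Mfap5 rose 8.53-fold. Srpx2 rose 65.7-fold although it is X-linked. Among 7 complement genes, 5 rose and 2 fell (median 1.54). The central component C3 went from 0.574 ± 0.126 to 9.35 ± 2.93 FPKM, the early proteases C1s1 and C1ra rose 5.14-fold and 3.92-fold, and Masp1 rose 3.14-fold.

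Endoplasmic reticulum chaperones and their partners rose in 13 of 23 cases and fell in 1 (median 0.19), and Hsp90b1 rose 1.26-fold. Of 30 lysosome genes, 13 rose and 7 fell (median 0.10). Of 31 proteasome subunits, 6 rose and 10 fell (median -0.03), and of 56 nuclear respiratory chain subunits, 12 rose and 20 fell (19 fell when adjusted over the list alone; median 0.00), beside 9 rises and no falls among 12 mitochondrially encoded genes. Of 7 metallothionein and zinc transport genes, 2 rose and 3 fell (4 fell when adjusted over the list alone; median -0.13), and the 2 metallothioneins differed: Mt2 rose from 31.7 ± 1.31 to 151 ± 24.9 FPKM while Mt1 stood at 148 ± 10.2 and 157 ± 27.4 FPKM.

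The real grouping of the 6 libraries gave 7140 called genes, and the highest of the other 9 of 10 splits gave 1. The real grouping alone (1 of 10 splits) gave as many, and 10 splits are too few for a share under 0.05. Every other split also puts libraries of both groups on each side. The group difference then widens the spread within a side, and few calls follow from that.

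Lower X-linked and higher Y-linked expression in NNMT cells is a pattern that calls for a check on the cells themselves. Matched on GC content, transcript length and expression, 0% of 10000 lists of autosomal genes had a median as low as the X-linked -0.70. This argues against those properties. Xist reached at most 0.006 FPKM in the NNMT libraries and 0.01 FPKM in the control libraries. These values argue against ongoing Xist-driven silencing of an X chromosome, and silencing kept up without Xist was not tested. A candidate explanation that stays open is a different number of X and Y chromosomes in the 2 populations: 12 of 12 windows along X had medians under -0.3, chromosome 4 changed sign near 80 Mb, and Ddx3y, Eif2s3y and Kdm5d in control cells were at 2.52% to 3.04% of their X-linked relatives against 63.0% to 75.4% in NNMT cells (Uty, 11.1% and 303%). For X, RNA cannot separate chromosome content from X-wide regulation by NNMT, and the population is confounded with the construct. X-wide regulation would not by itself cover the change of sign on chromosome 4 or the rise of 4 single-copy Y genes (13.3-fold to 18.2-fold). In control cells these 4 stood at 6.34 ± 0.85% of their NNMT level, whereas their share of the X-linked relatives ran from 2.52% to 11.1%. Control reads on Y may still come from the X copies. If chromosome content differs, clonal drift or selection of the populations could add to any of the gene differences, including those on other chromosomes.

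For the lower mitosis, ribosomal protein and cholesterol synthesis lists, the medians outside X, Y, 4 and 16 were -0.57 (SE 0.044), -0.17 (SE 0.038) and -0.42 (SE 0.084). The highest of them, -0.173, lay below 0 by more than its SE. Lower dosage of the members that lie on X and chromosome 4 is thus not the whole cause. Effects of such dosage on genes elsewhere were not tested and stay open. For ribosomal proteins 0 is a weak reference, since lists of other genes matched to the full list had a median of -0.184. Outside X, Y, 4 and 16 the ribosomal list passed camera at the preset correlation (adjusted p = 4.87e-08) and not with an estimated one (adjusted p = 0.638 with an estimated correlation, for each of the 3 lists). Matched lists of other genes had a median as low in 0% of 10000 draws for mitosis and for cholesterol synthesis. For ribosomal proteins they did in 12.8% of draws, and in 5.32% with other ribosomal protein and predicted genes kept out of the pool, so length, GC content and expression level stay open there, as does scaling, since quantile normalization moved the list's median from -0.23 to -0.04. Slower division of the NNMT cells, as an effect of NNMT or of the population, may underlie the mitosis values and was not tested.

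The rise of Nnmt was 2.53-fold. A copy number change of chromosome 9 as a whole does not account for it, since Nnmt lay at the 98.2nd percentile of the 602 other tested genes there, whose median was 0.15. If the mouse annotation counts the construct sequence only in part, the rise would appear smaller than it is. Gene totals cannot decide this, because read positions and the species of the construct were not used here. Nor can gene totals tell transcripts of the construct from those of the cells' own Nnmt gene. The population is confounded with the construct, and 168 genes rose by more than Nnmt.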
